A study of Mus musculus with 7 samples.

How the data were processed

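Total RNA of sorted mouse mammary cells was amplified by whole transcriptome amplification and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values were probe set intensities on a linear scale, 1 column per array for 7 arrays. RMA and the affy package are named in the submitters' processing notes; their versions, settings, order and any adjustment between sets of arrays were not given in the sources used here. The design had assumed log2 values, so log2 of the deposited intensity was taken first. The protocol text attached to the adult samples describes the embryonic preparation, so how the adult cells were prepared was not given in the sources used here. Whether the embryonic and adult arrays were summarised in separate runs and then centred on each other is not stated by any label. Levels set across the 2 sets of arrays carry that limit.

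The table held 45141 rows; 4 without values and 104 control probe sets were left out, and 45033 probe sets were used. The platform annotation gave 1 gene symbol for 28895 of them and several for 551, and 15587 were unlisted and unnamed here. Entrez identifiers matched 28686 single-gene probe sets to the gene table, and 0 symbols were updated. The probe set with the highest mean over all arrays stood for each of 17096 genes, 7178 of which had more than 1 probe set. A background level of 5.44 on the log2 scale (an intensity of 43.4) was the 95th percentile of 133 probe sets of 116 genes restricted to other organs; 9318 genes lay above it by their mean. Control probe sets for RNA integrity differed little: the 3' minus 5' log2 difference ran from -0.50 to -0.36 for Actb and from -0.31 to -0.21 for Gapdh. Embryonic levels in the table sat near the adult mean for most probe sets. These values therefore cannot show that RNA quality was alike in the embryonic and adult sets.

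Groups were taken from the sample labels. Limma (version 3.58.1 in R 4.3.3) fitted 3 group means to the log2 intensity over all 7 arrays with eBayes, leaving 4 residual degrees of freedom and a prior of 2.29. Contrasts were luminal minus basal, embryonic minus basal and embryonic minus luminal. A gene changed when its Benjamini-Hochberg adjusted p was under 0.05 and the difference at least 2-fold. The 3 embryonic arrays were also set against the 4 adult arrays as 2 groups. Lineage position was the median over changed luminal-high or basal-high genes of embryonic minus basal over luminal minus basal, per embryonic array. The 25 gene lists, the tests and the rule for named genes were fixed before the data were examined: sort and driver genes first, then up to 8 genes per direction with the largest difference among changed genes above background whose arrays do not overlap and whose names are not predicted or clone names, and for each list up to 4 changed members per direction by adjusted p and at most 2 that did not pass, in list order. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a contrast. The lists covered basal keratin, smooth-muscle contractile, luminal keratin, hormone receptor positive, milk and secretory, placode, WNT, Notch, Hedgehog, BMP and TGF-beta, mitosis, DNA replication, oncofetal, imprinted, chromatin, basement membrane, antigen presentation, glycolysis, stress and differentiated epidermis genes, and markers of fibroblasts, endothelium, leukocytes, erythroid cells and neural crest.

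Structure between sets of arrays was examined by exact ties of deposited intensities, by the 35 splits of the arrays and by simulated median polish of 1000 probe sets of 11 probes. List medians in single-array differences were placed among 10000 random lists of the same size matched on mean level. Random lists leave out how members of a list vary together, so an extreme percentile is no test of a difference. The fit was tested on simulated data: with 200 of 17096 genes changed between luminal and basal arrays, it recovered 78% of changes of 1.5 and 98% of changes of 3 on the log2 scale, with 2 false calls among 178. The variance ratio used for centring was 0.982 in simulated unchanged arrays, 10.4 in simulated arrays with differences and 1.1e-30 in simulated arrays centred exactly. Alternatives covered probe set choice, dim genes, normalization, the variance prior, array weights, fold minimums, the groups in the fit, a replicate block, each replicate left out, reference levels for lineage position and the list test; those added after seeing the data averaged embryonic replicates 1 and 2 as 1 sample and counted list members on the adult arrays alone or without a luminal array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.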

Results

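Gene expression was measured on Affymetrix mouse arrays in sorted mammary cells of 3 kinds, 7 arrays in all. The embryonic cells came from female embryos at embryonic day 14, with 3 arrays of 2000, 2000 and 813 cells. They were high in surface CD49f (the integrin alpha 6 encoded by Itga6) and in a GFP reporter of the gene Lgr5. Each embryonic replicate was a pool of the female embryos of a litter. The adult cells carried YFP 8 weeks after tamoxifen had switched on a Cre recombinase driven by keratin 8 (luminal cells, 2 arrays) or keratin 5 (basal cells, 2 arrays), and were marked in the labels as analysed again from earlier work. Nothing in the labels says whether the adult replicates came from separate animals, so p-values measure only the spread between these arrays. The median log2 intensity of probe sets ran from 5.04 to 5.07 over the 7 arrays. Per array, 9090 to 9335 of the 17096 genes tested (53.2% to 54.6%) lay above the background level. The small number of arrays limits the precision of every value.

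Before any comparison, the embryonic and adult arrays were set against each other over 45033 probe sets. The mean log2 intensity of the 3 embryonic arrays minus that of the 4 adult arrays had an SD of 0.09 over probe sets, against 0.49 for luminal minus basal. The embryonic mean lay within 1 replicate standard error of the adult mean for 95.03% of probe sets, where replicate error without any difference allows 62.6%. Among the 35 ways to split the 7 arrays into 3 and 4, the real split had the lowest SD, and the other splits had SDs of 0.13 to 0.34. Values were identical in embryonic replicates 1 and 2 for 16913 probe sets (37.6%), in replicates 1 and 3 for 8006 and in replicates 2 and 3 for 8057. Between adult arrays 52 to 94 probe sets were identical (at most 0.209%), and between the 12 pairs of an embryonic and an adult array none was. In simulated median polish summaries, 60.1% of probe sets tied between a pair of arrays when 3 arrays were summarised in 1 run, 0% when 4 were and 10.2% when 7 were. Embryonic levels in the table thus sat near the adult mean for most probe sets. Levels, counts and positions that set embryonic against adult arrays describe the table, and carry little information on how the cells differed.

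**Figure D1:**
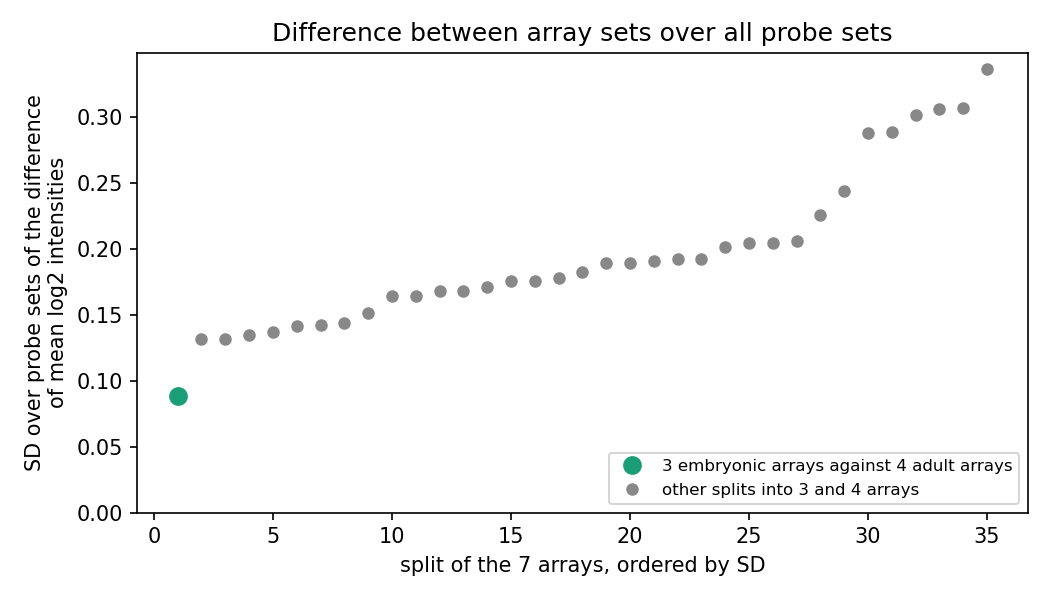
SD over probe sets of the difference of mean log2 intensities (vertical axis) for each of the 35 splits of the 7 arrays into 3 and 4, ordered by SD (horizontal axis). The split of embryonic against adult arrays (large point) has the lowest SD, 0.09, and the other splits (grey points) lie between 0.13 and 0.34.

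Adult luminal and basal cells differed in the genes that mark each layer, and this comparison lies within the adult arrays. Basal cells had higher Krt5, the keratin whose promoter drove the basal label, with a log2 difference, luminal minus basal, of -2.75 ± 0.32 (SE, n = 2 and 2 arrays, limma adjusted p = 0.0106). Wif1, a secreted WNT inhibitor (-4.26 ± 0.59), Tenm2 (-4.22 ± 0.80) and Lgr5 (-3.90 ± 0.44) were also higher in basal cells. Lgr5 had a mean log2 intensity of 10.02 in basal and 6.13 in luminal cells. Scn7a (-3.81), Gfra1 (-3.79), Ecrg4 (-3.77), the chemokine gene Cxcl14 (-3.65) and Igfbp3 (-3.62) were higher in basal cells too. On the luminal side, the angiotensin receptor gene Agtr1a (2.92 ± 0.16) and Foxa1, a transcription factor of hormone receptor positive cells (2.71 ± 0.25), were higher. So were Slc35f3 (2.69), Padi2 (2.68), Plac8 (2.65), Bex1 (2.64), Nipal1 (2.62) and Dnaic1 (2.52). Among these, luminal Wif1 (4.22), Scn7a (4.65) and Ecrg4 (5.13) and basal Agtr1a (4.89), Foxa1 (4.54), Slc35f3 (5.05) and Plac8 (4.85) lay below the background level of 5.44. The size of such differences, 13 among the 74 named genes that changed, is therefore not exact, and their order is not read. Krt8, whose promoter drove the luminal label, had a difference of 0.40 ± 0.15 and Itga6 one of -0.45 ± 0.16, and neither passed the test (limma adjusted p = 0.121 and 0.118).

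In all, 939 of 17096 genes changed, by at least 2-fold with a Benjamini-Hochberg adjusted p under 0.05 in limma, and a gene that missed either criterion is given as not passing. Of these, 490 were higher in luminal and 449 in basal cells, and in all 939 the luminal and basal arrays did not overlap. Of the 156 that differed at least 4-fold, 29 were higher in luminal and 127 in basal cells. None of the 116 silent genes was called in limma, by which 5352 of all genes had an unadjusted p under 0.05. The count depended on single arrays: it was 60 without luminal replicate 1, 148 without luminal replicate 2, 180 without basal replicate 1 and 377 without basal replicate 2. Each of these fits left 1 array in a group, which was assumed to vary like the other groups. The fit pooled the spread of all 7 arrays, the tied embryonic values included. The 4 adult arrays alone gave 1165 genes, 935 of them shared with the 939. Among genes named below as not passing, Col1a2, Lef1, Tnfsf11, Csn1s2b, Ihh, Lin28a and Krt1 had every group mean below the background level. Their small differences do not show unchanged expression.

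Of 17 measured basal keratin, p63 and hemidesmosome genes, 9 changed, all higher in basal cells. Cdh3, the P-cadherin gene (-3.01 ± 0.16), Lama3, a laminin chain of hemidesmosomes (-2.92 ± 0.32), Krt5 and Dkk3 (-2.26 ± 0.28) changed, and Krt15 (-0.77) and Itga6 did not pass. The list's median was -1.71 and camera called it (adjusted p = 2.02e-12), with an adjusted p = 0.0893 with an estimated correlation. Smooth-muscle contractile genes were higher in basal cells in 8 of 18 members (9 adjusted over the list alone), among them Cald1 (-2.33 ± 0.14), Cnn1 (-3.06 ± 0.42), Actg2 (-2.32 ± 0.34) and Myh11 (-3.09 ± 0.62). Acta2, the smooth-muscle actin gene, had a difference of -2.65 ± 0.67 that did not pass (limma adjusted p = 0.0520), and Tpm1 had -0.43. That list's median was -1.03 (camera adjusted p = 2.84e-09; adjusted p = 0.0893 with an estimated correlation). Basement membrane genes were higher in basal cells in 8 of 18 members, including Lama1 (-2.10 ± 0.17), Hspg2 (-1.47 ± 0.15), Col4a6 (-1.57 ± 0.26) and Col4a1 (-1.71 ± 0.29), while Npnt was higher in luminal cells (1.79 ± 0.31). Lama2 (-0.31) and Lamb2 (-0.80) did not pass (median -0.90; adjusted p = 0.0893 with an estimated correlation). Beside these 3 lists, fibroblast markers had a median of -1.02 and endothelial markers one of -1.25. The mean log2 intensity of Col1a1, an abundant fibroblast transcript, was 10.87 in basal and 9.50 ± 1.30 (SD, n = 2) in luminal cells.

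Luminal keratin, claudin and transcription factor genes were higher in luminal cells in 10 of 20 members (12 adjusted over the list alone). Wfdc2 (1.66 ± 0.20), the transcription factor gene Ehf (1.59 ± 0.25), the tight junction gene Cldn3 (1.39 ± 0.23) and Prom1 (1.86 ± 0.32) changed, and Krt8 and Krt18 (0.68 ± 0.14) did not pass. The median was 1.15 and camera called the list (adjusted p = 9.19e-08), with an adjusted p = 0.164 with an estimated correlation. Between the basal arrays, replicate 2 minus 1, its median was 0.35, with 17 of 20 members higher. That of the hormone receptor positive list was 0.23 there, with 10 of 14 higher. Genes of hormone receptor positive cells were higher in luminal cells in 7 of 14 members: Foxa1, the progesterone receptor gene Pgr (1.88 ± 0.22), Cited1 (2.24 ± 0.26) and Wnt4 (1.73 ± 0.22) changed. Tnfsf11 (0.18) and Wnt5a (0.54) did not pass (median 1.42, camera adjusted p = 2.69e-06, adjusted p = 0.0893 with an estimated correlation). Milk and secretory progenitor genes were higher in luminal cells in 4 of 19 members, Elf5 (1.68 ± 0.19), Kit (1.40 ± 0.27), Csn1s1 (1.12 ± 0.25) and Aldh1a3 (1.81 ± 0.43). Kit lay below the background level in both groups (5.42 and 4.02), as did Elf5 in basal cells (4.98). The luminal arrays differed from each other in this list, with a median of -0.19 for replicate 2 minus 1 and 4 of 19 members higher. The caseins Csn1s2a (0.31) and Csn1s2b (0.15) did not pass (median 0.54; adjusted p = 0.336 with an estimated correlation).

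**Figure D2:**
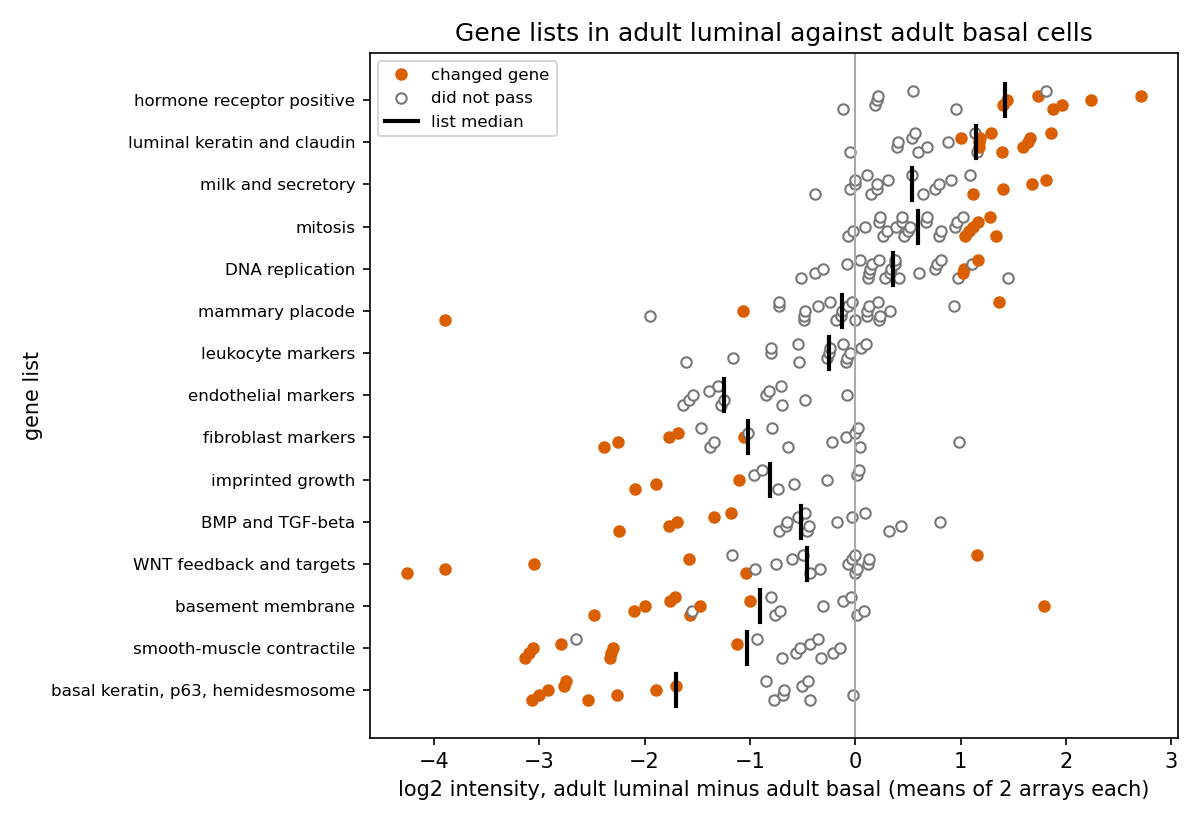
Log2 intensity of adult luminal minus adult basal cells, means of 2 arrays each (horizontal axis), for the measured members of 15 gene lists (vertical axis); filled points are genes that changed, open points are genes that did not pass, and black bars are list medians. The basal keratin list has a median of -1.71 and the hormone receptor positive list one of 1.42, with fibroblast markers at -1.02 and endothelial markers at -1.25.

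A minority of cell cycle genes passed. Of 26 mitotic genes 6 changed, all higher in luminal cells, among them Birc5 (1.17 ± 0.17), Kif11 (1.11 ± 0.20), Cdk1 (1.04 ± 0.19) and Mki67, the antigen of cycling cells (1.27 ± 0.27). Ccnb2 (0.26) and Ccna2 (0.97) did not pass (median 0.59; adjusted p = 0.335 with an estimated correlation). Of 26 DNA replication genes 3 were higher in luminal cells, Mcm6 (1.04 ± 0.17), Tyms (1.02 ± 0.22) and Prim1 (1.16 ± 0.28). Mcm2 (1.45 ± 0.37) and Mcm3 (0.77) did not pass (median 0.36; adjusted p = 0.335 with an estimated correlation). Both lists also differed between the luminal arrays, with medians of 0.36 for mitosis and 0.17 for DNA replication, replicate 2 minus 1. Between the basal arrays these medians were 0.09 and 0.26. Imprinted growth genes were higher in basal cells in 3 of 10 members, the cell cycle inhibitor gene Cdkn1c (-1.89 ± 0.27), the growth factor gene Igf2 (-1.10 ± 0.18) and the non-coding RNA Meg3 (-2.09 ± 0.35). Dlk1 (-0.97) and Peg3 (-0.74) did not pass (median -0.81; adjusted p = 0.111 with an estimated correlation). Fibroblast (-1.02) and endothelial (-1.25) medians moved with this list. Between the luminal arrays the imprinted list, at 0.21 for replicate 2 minus 1, also moved with fibroblast (0.38) and endothelial (0.64) markers.

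In the signalling lists a few members each passed, most of them higher in basal cells. Of 20 WNT feedback and target genes, 5 were higher in basal cells, among them Wif1, Lgr5, Prickle1 (-1.58 ± 0.19) and Nkd2 (-1.03 ± 0.14), and Ccnd1, the cyclin D1 gene, was higher in luminal cells (1.16 ± 0.16). Axin2, a common readout of WNT signalling (-0.60), and Lef1 (-0.03) did not pass, and the list's median was -0.46 (adjusted p = 0.278 with an estimated correlation). Of 18 BMP and TGF-beta genes, 5 were higher in basal cells, among them Smad7 (-1.34 ± 0.18), Id4 (-2.24 ± 0.31), Bambi (-1.77 ± 0.33) and Bmp7 (-1.69 ± 0.37). Bmp2 (-0.47) and Bmp4 (-0.46) did not pass (median -0.51; adjusted p = 0.335 with an estimated correlation). The Notch ligand genes Dll1 (-2.40 ± 0.24) and Jag1 (-1.65 ± 0.22) were the 2 of 17 Notch genes that changed. The receptor genes Notch1 (-0.30) and Notch2 (-0.11) did not pass (median -0.21; adjusted p = 0.364 with an estimated correlation). Of 11 Hedgehog genes, the co-receptor genes Gas1 (-2.16 ± 0.29) and Boc (-1.43 ± 0.35) were higher in basal cells. The ligand genes Shh (0.13) and Ihh (-0.21) did not pass (median -0.37; adjusted p = 0.335 with an estimated correlation). Of 25 mammary placode and bud genes, Lgr5 and Bcl11b (-1.06 ± 0.16) were higher in basal and Msx2 (1.36 ± 0.22) in luminal cells. Lef1 and Tbx3 (0.22) did not pass, and camera did not call the list (median -0.13, adjusted p = 0.106). Fibroblast (-1.02) and endothelial (-1.25) medians lay on the basal side too. Between replicates 2 and 1 of the same lineage, medians differed by 0.33 for WNT and 0.38 for BMP and TGF-beta genes in basal arrays and by 0.21 for Hedgehog genes in luminal arrays, with endothelial markers at 0.73 and 0.64.

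Among markers of other cell types, few passed. Of 17 fibroblast markers 5 were higher in basal cells, among them Postn (-2.39 ± 0.16), Mfap5 (-1.06 ± 0.11), Col5a1 (-1.76 ± 0.27) and Col6a1 (-1.68 ± 0.28). Mfap5 lay below the background level in both groups (4.17 and 5.23), as did Col1a2 (5.18 and 5.18). Col1a1 (-1.38 ± 0.56) and Col1a2 (0.00) did not pass (camera adjusted p = 5.60e-05; adjusted p = 0.335 with an estimated correlation). None of 13 endothelial markers changed over all genes tested, and 6 were at least 2-fold higher in basal cells adjusted over the list alone. Their median was -1.25 (camera adjusted p = 1.61e-05; adjusted p = 0.335 with an estimated correlation), with Pecam1 at -1.63 ± 0.72 and Cdh5 at -1.58 ± 0.55. None of 15 leukocyte markers changed (median -0.25; adjusted p = 0.564 with an estimated correlation), with Cd74 at -0.80; 7 of the 15 lay above background in an adult lineage, and Ptprc (-0.09) did not. None of 8 erythroid markers changed (median 0.03, camera adjusted p = 0.938), with Hba-a1 at 0.40; 2 of the 8 lay above background, and Hba-x (-0.03) did not. Of 11 melanocyte, Schwann and neural crest markers the receptor gene Erbb3 was higher in luminal cells (1.85 ± 0.32). Dct (0.12) and Tyr (0.03) did not pass, and the median of 0.02 differed in sign from camera's direction (adjusted p = 0.847).

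The remaining lists moved in few members. Among immediate early and dissociation stress genes 2 of 17 were higher in basal cells, Egr2 (-2.30 ± 0.53) and Socs3 (-1.52 ± 0.37). The basal arrays differed more from each other in this list (replicate 2 minus 1, median 0.37, 15 of 17 higher), with Egr2 at 9.52 and 10.57 and Socs3 at 7.58 and 8.45. Fos (-0.65) and Fosb (-0.29) did not pass (median -0.29; adjusted p = 0.370 with an estimated correlation). Vegfa (-1.25 ± 0.27) was the 1 of 13 glycolysis and hypoxia genes that changed, with Slc2a1 at -0.27 and Pgk1 at 0.02 (median -0.09, camera adjusted p = 0.175). Krt6a (1.22 ± 0.23) and Sbsn (1.06 ± 0.21) were higher in luminal cells among 18 genes of differentiated epidermis. Krt1 (0.41) and Krt10 (0.13) did not pass (median 0.07, camera adjusted p = 0.847). Psmb8 (1.20 ± 0.25) was the 1 of 14 antigen presentation and interferon genes that changed, with H2-K1 at 0.01 and H2-D1 at 0.26 (median 0.08, camera adjusted p = 0.847). No member changed among 10 oncofetal genes (median 0.03), with Lin28a at -0.12 and Hmga2 at 0.16, or among 16 chromatin regulators (median 0.04), with Ezh2 at 0.24 and Eed at -0.03 (camera adjusted p = 0.847 for each). By camera 17 of the 25 lists were called, 0 were with an estimated correlation, and fry called 13. At the preset correlation camera did not call the placode, oncofetal, chromatin, antigen presentation, glycolysis, differentiated epidermis, erythroid and neural crest lists. Lists for which only an adjusted p with an estimated correlation was given above were all among the 17. Counts of changed members rested on both luminal arrays: basal keratin genes numbered 1 of 17 and contractile genes 1 of 18 without luminal replicate 1 and likewise without luminal replicate 2. Luminal genes numbered 0 and 1, and hormone receptor positive genes 0 and 0.

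**Figure D3:**
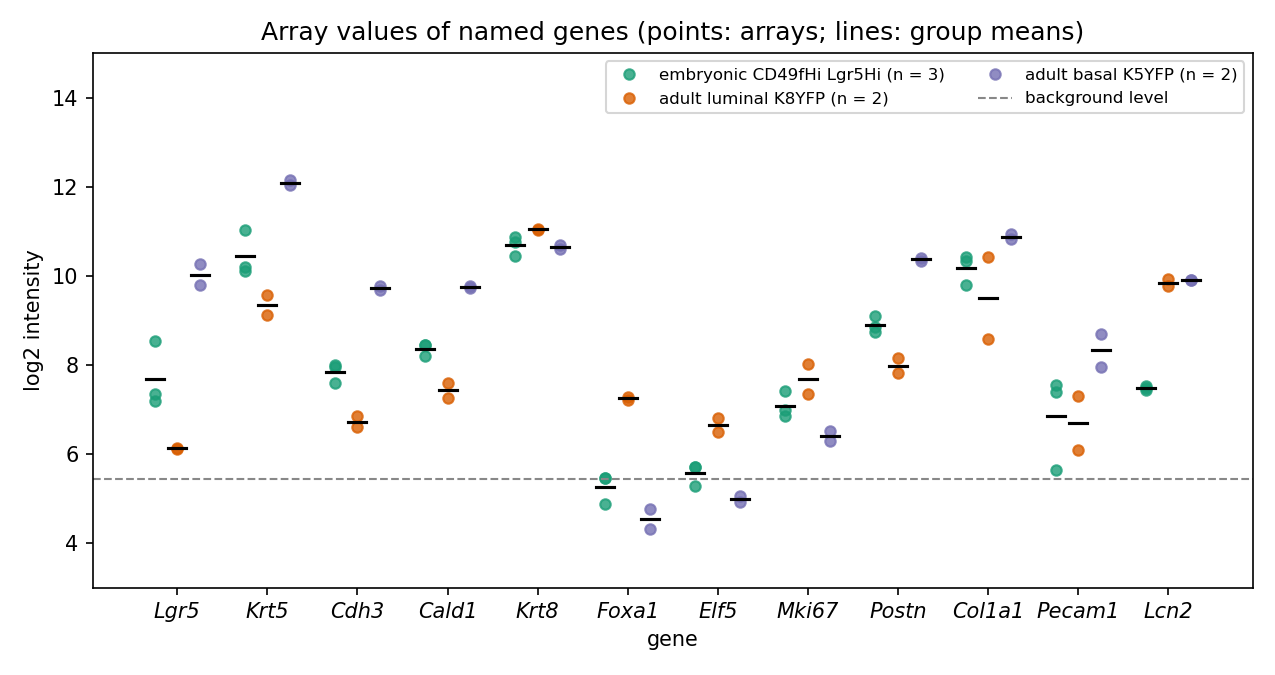
Log2 intensity (vertical axis) of 12 genes (horizontal axis) on each of the 7 arrays, as points coloured by group with group means as black lines and the background level as a dashed line. Lgr5 lies at 10.02 in basal and 6.13 in luminal cells with the embryonic arrays between, and Lcn2 lies at 7.49 in embryonic cells against 9.85 and 9.90 in luminal and basal cells.

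Embryonic cells against adult basal cells gave 12 changed genes, all lower in the embryonic columns. Those named by the rule were Scn7a (-2.55 ± 0.22, embryonic minus basal), Ecrg4 (-2.53 ± 0.24), Lcn2, the lipocalin 2 gene (-2.42 ± 0.08), Cdh3 (-1.88 ± 0.15), Postn (-1.47 ± 0.14), Cald1 (-1.40 ± 0.13), Pdk4 (-1.39 ± 0.12) and Cpne8 (-1.38 ± 0.08), with n = 3 and 2 arrays. Lgr5, on which the embryonic cells were sorted, stood at 7.68 ± 0.74 (SD, n = 3) in the embryonic columns, and its difference of -2.34 ± 0.40 did not pass (limma adjusted p = 0.174). Krt5 (-1.65 ± 0.29), Itga6 (-0.29 ± 0.15) and Krt8 (0.05 ± 0.13) did not pass either. In limma 0 genes were higher in the embryonic columns, and 1581 genes had an unadjusted p under 0.05 in either direction. Over probe sets, embryonic minus adult means ran from -0.413 at the 1st to 0.039 at the 99th percentile. The lack of higher genes is therefore not read as an embryonic trait. Camera called 16 of 25 lists and 0 with an estimated correlation (lowest adjusted p = 0.0539). Across genes, embryonic minus basal followed luminal minus basal at r = 0.940 (slope 0.499), so these calls are not read as separate from that comparison. Of the 12 genes, 11 had also changed between luminal and basal cells. Scn7a, Pdk4 and Cpne8 had 3 identical embryonic values, so their standard errors hold no embryonic spread. Embryonic Cpne8 (4.96) lay below the background level of 5.44, so the size of its difference is not exact. With embryonic replicates 1 and 2 averaged as 1 sample, an alternative chosen after seeing the data, 1 gene changed. The count was 89 without embryonic replicate 3, 2 and 1 without embryonic replicates 1 and 2, 4 without either luminal replicate and 0 without either basal replicate.

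Embryonic cells against adult luminal cells gave 4 changed genes, all lower in the embryonic columns: Lcn2 (-2.36 ± 0.08), Agtr1a (-2.12 ± 0.15), Tmprss13, a membrane serine protease gene (-1.46 ± 0.10), and Vill (-1.42 ± 0.10). Lgr5 (1.56 ± 0.40), Krt5 (adjusted p = 0.232 in limma), Itga6 (0.16 ± 0.15) and Krt8 (-0.35 ± 0.13) did not pass. In limma 0 genes were higher in the embryonic columns, and 2060 had an unadjusted p under 0.05. Camera called 14 of 25 lists and 0 with an estimated correlation (lowest adjusted p = 0.0798). Across genes, embryonic minus luminal followed basal minus luminal at r = 0.941, so these calls too are not read as separate from the luminal and basal comparison. Tmprss13 and Vill had 3 identical embryonic values, and 1 gene changed with embryonic replicates 1 and 2 averaged. The count was 217 without embryonic replicate 3, 2 and 1 without embryonic replicates 1 and 2, and 1 without either luminal replicate.

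Lcn2 was the 1 gene lower in the embryonic columns than in both adult lineages, and 0 genes were higher than in both in limma. At an unadjusted p under 0.05 in each comparison the numbers were again 1 and 0. Its mean log2 intensity was 7.49 ± 0.05 (SD, n = 3) in embryonic, 9.85 ± 0.11 in luminal and 9.90 ± 0.01 in basal cells. Without either basal replicate 0 genes were lower than in both. Lcn2 was also the 1 gene changed when the 3 embryonic arrays were set against all 4 adult arrays, where 2 of 17096 genes (0.0117%) had an unadjusted p under 0.05. The comparisons with basal and with luminal cells share the embryonic arrays. Their log2 differences correlated across genes at r = -0.768 with a covariance of -0.07, where unchanged groups simulated 20 times gave 0.398 and 0.01. The simulated groups held no difference between luminal and basal cells. Embryonic levels near the adult mean give a negative r where the adult lineages differ, so no conclusion is drawn from the gap. Independent lists of these sizes would share 0.00281 lower genes. The 2 comparisons share arrays, so that number is no measure of chance.

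The lineage position of the embryonic arrays, 0 at the adult basal and 1 at the adult luminal mean, was 0.343 ± 0.0230 (SD, n = 3) over the 490 luminal-high genes and 0.624 ± 0.0519 over the 449 basal-high genes. The embryonic mean lay between the adult means for all 490 and all 449 genes, which embryonic levels near the adult mean give by construction. Of the luminal-high genes 3 differed from luminal cells only, 0 from basal cells only, 0 from both and 487 from neither. Of the basal-high genes 11 differed from basal cells only, 0 from luminal cells only, 0 from both and 438 from neither. A level midway between the adult means can differ 2-fold from either only where these differ at least 4-fold. That held for 156 of the 939 genes, so these counts largely describe the table. Both positions put the embryonic level of these genes in the table below midway between the adult means, and no embryonic trait is read from this. Luminal-high position was 0.476 without basal replicate 2, and 0.215 with genes chosen on adult replicates 1 and levels taken from replicates 2. Luminal-high genes differing from luminal cells only numbered 165 without embryonic replicate 3, and basal-high genes differing from basal cells only numbered 74.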

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

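All settings here were chosen before the data were examined except the averaging of embryonic replicates 1 and 2 and the counts of list members on the adult arrays alone or without a luminal array. The 939 genes changed between luminal and basal cells became 605 with array weights, 2223 with no fold minimum, 1839 with a 1.5-fold minimum and 80 with limma's treat against 1.5-fold, and ran from 60 to 1178 when each replicate was left out in turn. A lone sample left in a group was assumed to vary like the other groups. The 12 genes of the embryonic and basal comparison became 25 with the mean of all probe sets, 7 without probe sets of shared or cross-hybridising type and 27 above background only. They became 1 with treat, 4 with the compared groups alone, 88 with the replicate block and 1 with embryonic replicates 1 and 2 averaged, and ran from 0 to 89 without a replicate. The 4 genes against luminal cells became 16 with the mean of all probe sets, 155 with array weights, 1 with treat, 182 with the replicate block and 1 with the averaging, and ran from 1 to 217. The 1 gene lower than in both lineages ran from 0 to 1, and the 1 gene against all adult arrays stayed 1 in every setting. Luminal-high position (0.343) became 0.371 with quantile normalization, 0.417 with no fold minimum, 0.392 with 1.5-fold and 0.215 with genes chosen on adult replicates 1 and levels from replicates 2, and ran from 0.305 to 0.476. Basal-high position (0.624) became 0.721 with that choice and ran from 0.565 to 0.659. No luminal-high gene differed at least 8-fold, so that setting gave no luminal-high value. The 3 luminal-high genes that differed from luminal cells only became 15 with the mean of all probe sets, 106 with array weights, 5 with no fold minimum, 5 with 1.5-fold, 0 with treat, 143 with the replicate block and 0 with the averaging, and ran from 0 to 165. Those that differed from both ran from 0 to 1. The 487 that differed from neither became 210 with array weights, 1398 with no fold minimum, 1141 with 1.5-fold and 30 with treat, and ran from 35 to 452. The 11 basal-high genes that differed from basal cells only became 24 with the mean of all probe sets, 6 without shared probe sets, 26 above background only, 0 with treat, 3 with the compared groups alone, 73 with the replicate block and 0 with the averaging, and ran from 0 to 74. Basal-high genes that differed from luminal cells only (0) became 11 with array weights and 13 with the block and ran from 0 to 23. Those that differed from both (0) became 5 and 10 and ran from 0 to 9. The 438 that differed from neither became 263 with array weights, 808 with no fold minimum, 681 with 1.5-fold and 50 with treat and ran from 22 to 454. The 17 lists called between luminal and basal cells became 0 with an estimated correlation and ran from 12 to 17 without a replicate. The 16 against basal became 0 and, with fry, 4, and ran from 10 to 17. The 14 against luminal became 0 and, with fry, 6, and ran from 11 to 16. A stricter or looser fold threshold on the same fit lowers or raises counts by construction. Leaving out embryonic replicate 3 raised counts, to 1178, 89 and 217 in the 3 comparisons of groups, and leaving out an adult replicate lowered the first of them. The cause of these and the other moves was not tested. No gene or list that was called in the main fit or in an alternative changed direction between them. Counts and positions could not be given as reversed, and a change of direction without a call was not counted. Of 123 named luminal and basal genes, 74 changed. Without luminal replicate 1, luminal replicate 2, basal replicate 1 and basal replicate 2 the calls of 68, 61, 57 and 48 were lost. Replicate numbers were not taken as pairs. For the same number, luminal and basal deviations correlated at 0.0794. Embryonic and luminal ones correlated at -0.167 and 0.0919, and embryonic and basal ones at -0.0137 and -0.0726. With 2 arrays in an adult group the deviations mirror each other, so these values cannot exclude pairing. The replicate block gave 1199 genes between luminal and basal cells. Its term for number 3 covered embryonic replicate 3 alone, so the block in effect also left that array out. Of the 939 genes, 898 lay above background in the higher group, and signal near background limits the rest.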

Other observations

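The tests of explanations here, and their bounds, were chosen after the values were seen; the count over splits was planned before the data were examined. A shift common to the embryonic arrays that is additive on the log2 scale would leave differences within the embryonic set unchanged. Another kind of adjustment could alter them, and whether or how the set was adjusted is not stated by any label. Embryonic replicate 3, of 813 cells, differed from the mean of replicates 1 and 2, of 2000 cells each, in the placode list, whose median was 0.23 higher on the log2 scale (percentile 99.8 among 10000 random lists matched on level, 15 of 25 members higher). Lgr5 itself was at 8.53 in replicate 3 against 7.18 and 7.34, Edar, the ectodysplasin receptor gene, at 6.34 against 5.42 and 5.58, and Sox11 at 7.59 against 7.08 and 7.06. Other placode genes were lower there, with Sostdc1 at 6.24 against 6.79 in both others and Msx2 at 5.59 against 6.03 and 6.07. Fibroblast (-0.46), endothelial (-0.36) and leukocyte (-0.33) medians were lower in the same array. The medians of DNA replication genes (0.25, percentile 99.7, 17 of 26 higher) and chromatin regulators (0.32, percentile 99.4, 10 of 16 higher) were also higher, while that of mitotic genes was lower (-0.18, percentile 4.8, 9 of 26 higher). So were those of milk and secretory (-0.20, percentile 2.07, 1 of 19 higher), stress (-0.15, percentile 2.17, 7 of 17 higher) and antigen presentation genes (-0.21, percentile 2.72, 4 of 14 higher). The median of contractile genes was lower (-0.25, percentile 0.29), but 7 of 18 were higher, Myh11 at 8.88 against 7.49 and 7.33 among them. Genes of differentiated epidermis were lower (-0.23, percentile 0.05, 1 of 18 higher), with 8 of 18 above background in an adult lineage. These are values of 1 array without a replicate check, and they come from 130 list medians examined over 5 differences. Among single genes, picked after their values were seen, Gem (2.66), Tenm2 (2.34) and Lgr4, an Lgr5 relative (1.70), were higher in replicate 3, and Krt4 (-2.06), Col14a1 (-1.65) and Pecam1 (-1.83) were lower.

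Embryonic levels lay near the adult mean for most probe sets. Cells that truly expressed each gene midway between the adult lineages would still scatter by replicate error, and 95.03% of probe sets within 1 standard error, against 62.6% allowed, argue against that. A candidate explanation is that the sets were centred on each other before deposit, though not exactly on log2 means, which gave 1.1e-30 when simulated: the variance of the embryonic minus adult mean was 0.331 of what replicate spread alone gives, and 0.324 with the spread of each set taken apart. Whether all 7 arrays were summarised in 1 run is not settled by simulation, since a simulated rate alone excludes nothing. At most 0.209% of probe sets tied between adult arrays, against 10.2% in a simulated run of 7 and 0% in 1 of 4. The ties within each set argue against 1 run for all 7, without settling it. Embryonic replicates 1 and 3 tied in 17.8% of probe sets, with an SD of 0.373 for their log2 difference. The luminal arrays were closer, at an SD of 0.251, yet tied in 0.115%. The remaining difference followed the adult spread across probe sets (r = -0.701), so it was not read as a trace of embryonic expression.

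In the comparison of 3 embryonic with 4 adult arrays, the real split gave 1 gene. At least as many came from 3 of the 35 splits of the arrays, the real one included. Embryonic levels near the adult mean left few genes to call in the real split, so no conclusion on chance is drawn from this count. The highest of the other splits, embryonic replicate 3 with both luminal arrays, gave 273, and replicate 3 with both basal arrays gave 58. The same splits with embryonic replicate 1 or 2 in its place gave 0, so the calls came where both the adult lineages and replicate 3 were set apart, a structure of the samples and not a measure of chance. The 1 gene of the real split was Lcn2, at an embryonic minus adult difference of -2.39, beyond its spread within any group (SD 0.05, 0.11 and 0.01), and why it stood apart was not tested.

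Fibroblast markers were lower in embryonic replicate 3 than in replicates 1 and 2 (median -0.46, below all 10000 random lists), with Col1a1 at 9.78 against 10.43 and 10.32 and Vim at 8.76 against 10.07 and 9.85. Fewer stromal and blood cells in that sort may account for this. Endothelial (percentile 0.28) and leukocyte (percentile 0.23) medians were low too, at -0.36 and -0.33, and Hba-a1 was at 10.84 against 11.67 and 11.92. Members of these lists vary together (estimated correlations of 0.696 and 0.615), which the random lists leave out. Of the epithelial lists, basal and luminal keratin genes moved little as sets in that array. The basal keratin median was 0 (percentile 32.9, 8 of 17 higher) and the luminal keratin median 0.05 (percentile 64.4, 11 of 20 higher). Contractile (-0.25), milk and secretory (-0.20) and differentiated epidermis (-0.23) medians were lower, and the placode median (0.23) was higher. The keratin gene Krt14 was at 9.71 against 10.37 and 10.93, and Trp63 at 8.91 against 7.90 and 8.95. These values therefore do not show that only stromal markers moved. The erythroid median, at percentile 7.8, missed the bound of 5 but decides little, since 0 of 8 members were higher and 2 of 8 lay above background in an adult lineage. The smaller input of replicate 3 stays open too, since 53.2% of genes lay above background there against 54.6% and 54.2%, and these cannot be told apart because 1 array holds both the smaller input and the shift. The sort on CD49f and the Lgr5 reporter would be expected to remove most such cells, and a change of expression within the sorted cells was not tested.

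As a list, fibroblast markers were higher in adult basal than luminal cells (median -1.02, luminal minus basal), with 3 of 17 members higher in luminal cells. The fibroblast gene Dcn overlapped between the lineages, at 10.43 and 9.67 in luminal and 9.79 and 10.21 in basal arrays. Stromal cells in the basal sort may contribute: the endothelial list, which shares no gene with the fibroblast list, had a median of -1.25 at percentile 0 of the random lists, with Pecam1 at 7.95 and 8.69 and Cdh5 at 7.85 and 8.48 in the basal arrays. Expression of the fibroblast-list genes by basal cells themselves stays open; 14 of 17 members lay above background in an adult lineage. Between replicates 2 and 1 the fibroblast list differed by 0.38 in luminal and 0.34 in basal arrays, with 14 of 17 members higher in each. Dcn went the other way between the luminal arrays (-0.75). The endothelial list differed by 0.64 and 0.73, at percentile 100 in each, so extreme percentiles also arose within a lineage. The leukocyte list differed by 0.46 and 0.19, and the basal keratin list by -0.05 and 0.04. The sort on YFP driven by keratin 5 would be expected to remove stromal cells, and the 2 explanations cannot be told apart for the fibroblast list.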
